A study of Homo sapiens with 6 samples.

How the data were processed

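RNA was measured in cells labelled MDA-MB-231, an established human line of triple negative breast cancer. They were taken 48 h after transfection with a control siRNA (siControl) or with siRNA against RNF31 (siRNF31). Each group held 3 libraries, and each library was deposited as its own table. Per the labels' protocols, cells were lysed in Trizol and libraries were prepared from total RNA by BGISEQ-500 protocols. The aligner, the quantification program, the genome build and the gene annotation are not given in the sources used here. The sequences of the siRNAs were not used here.

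The deposited values are FPKM (fragments scaled by transcript length and by the mapped fragments of the library), per the file headers, printed to 2 decimals. Each table listed the same 17645 genes by NCBI Gene ID and symbol, and 17577 of these IDs were found in the RefSeq gene table for GRCh38.p14, which was used for names and gene order only. FPKM is a relative unit. A gene that takes a larger share of the fragments lowers the values of all others, and the division by length depends on the transcript model chosen. Read counts were not derived from these values, so the depth is unknown and no counting interval or detection floor is given. The totals of the FPKM columns ran from 421755 to 463457 and are not depths.

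Because the deposited unit was FPKM, the branch of the design written for normalized values was used and no model of read counts was fitted. Values were taken as deposited and transformed to log2(FPKM + 1). Genes with FPKM of at least 1 in at least 3 of the 6 libraries were kept, which left 11346 genes. The groups were compared with limma 3.58.1 in R 4.3.3, with an intensity trend and robust empirical Bayes moderation. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p below 0.05. A gene was counted as changed by at least 2-fold when it was called and its absolute log2 fold change was at least 1. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Where a fold or a percentage of mean FPKM is given, it is the ratio of the group means.

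Gene lists were fixed before the data were examined. Of 31 lists, 29 had at least 5 tested members and were tested with camera, a competitive test in limma that sets a list against all other tested genes, with a preset correlation between genes of 0.01 and adjustment over the 29 lists. Genes were named by a rule fixed at the same time. It took 13 genes of LUBAC, the Hippo and NF-kB pathways and growth control whatever their result, and the 12 largest changes in each direction with mean FPKM of at least 2 and groups that did not overlap, leaving out symbols of antisense and non-coding loci. It also took up to 4 called members with the largest change in each list and the 5 most abundant called genes per direction. A gene outside this rule is said to be so where it is named, except where it is given as a member of a list described in the same sentence or as a marker.

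Alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, median of ratios scaling, limma without the intensity trend, the replicate number as a block, and leaving out each of the 6 libraries. For the lists they also included camera with an estimated correlation and fry, a rotation test. Scaling to a common sum, quantile normalization, removal of a GC and length trend, leaving out 2 libraries together and leaving out genes with certain 3′ UTR sequences were added after the data were seen. For the GC and length trend, a spline fit with 5 degrees of freedom for each property was removed from every library. The properties came from GENCODE release 29 transcripts (GRCh38) matched by Gene ID, and 99.4% of tested genes had both. The annotated 3′ UTRs of the same release were searched for 7-base sequences. Each sequence present in at least 50 genes was regressed on log2 fold change with UTR length, UTR GC content and mean expression as covariates.

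The steps were tested on simulated data. For siRNF31 against siControl, FPKM of 11346 genes were simulated with 200 genes changed, and limma called 70% of the 1.5-fold changes and 94% of the 2-fold changes, while 2.38% of the calls were unchanged genes. Camera gave an unadjusted p under 0.05 for 2% of 200 random lists of 25 genes and for 100% of 20 lists shifted by 0.5 on the log2 scale. Noise was drawn independently for each gene, so these camera rates do not cover lists whose members are correlated. For the sequence search over 11173 genes, those that carried a chosen 7-base sequence were shifted by -0.3 on the log2 scale. That sequence ranked 1 of 16189. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.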

Results

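The data set describes what happened to the transcriptome of cells labelled MDA-MB-231 when RNF31 was silenced. RNF31, also called HOIP, is the catalytic subunit of the linear ubiquitin chain assembly complex (LUBAC), which acts in NF-kB signalling. The series asks about the function of RNF31 in triple negative breast cancer. Libraries were made from 3 samples transfected with siControl and 3 transfected with siRNF31, 48 h after transfection. Expression was deposited as FPKM for 17645 genes, and 11346 of them were tested. Pearson correlations of log2 values ran from 0.993 to 0.998 within groups and from 0.941 to 0.949 between groups. The first principal component held 89.0% of the variance and separated the groups. The next held 7.18% and set siControl replicate 1 and siRNF31 replicate 3 apart from the other 4 libraries, so each group held 1 of these libraries. Nothing in the labels says that the replicates were separate cultures, and the p-values then measure only the spread between these libraries, which may be technical.

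RNF31 (Gene ID 55072) was lower in every siRNF31 library. Its FPKM were 11.34, 10.7 and 10.57 in siControl and 1.92, 2.12 and 1.86 in siRNF31. The mean fell from 10.9 ± 0.412 to 1.97 ± 0.136 (SD, n = 3 each), which left 18.1% of the siControl level. The log2 fold change was -2.0 with a standard error of 0.067 (limma, adjusted p = 1.29e-07). The partner subunits of LUBAC, RBCK1 and SHARPIN, did not pass the test. RBCK1 measured 43.0 ± 1.65 FPKM in siControl and 44.1 ± 1.53 in siRNF31 (limma, adjusted p = 0.59), and SHARPIN 44.7 ± 2.60 and 43.8 ± 2.80 (adjusted p = 0.73). Among the genes next to RNF31 in the RefSeq order, PSME2 fell and REC8 rose. The list of 11 tested neighbours had a median log2 fold change of -0.05 with 3 members higher and 4 lower, and adjusted over the list alone 3 were higher and 5 lower. The list did not pass (camera, adjusted p = 0.97).

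Silencing of RNF31 came with a broad change in expression. NF-kB targets, interferon-stimulated genes, antigen presentation genes and matrix protease and integrin genes were lower in siRNF31. Immediate early genes, histone genes and targets of the stress transcription factor ATF4 were higher, and targets of the Hippo effectors YAP and TAZ moved upward on balance. In all, 3022 genes were higher and 4141 lower, together 63.1% of those tested. By at least 2-fold, 401 genes were higher and 489 lower, and under median of ratios scaling 457 were higher and 406 lower. The values of the groups did not overlap for 67.2% of tested genes, where chance gives 10%. The median log2 fold change of all genes tested was -0.06. Of the 29 lists, 12 passed the camera test, 7 upward and 5 downward, and 2 of these, the histones and the interferon-stimulated genes, also passed with an estimated correlation.

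NF-kB targets fell as a list, with 23 of 27 tested members lower and 3 higher and a median log2 fold change of -1.03 (camera, adjusted p = 1.08e-05). Adjusted over the list alone, 23 were lower and 3 higher as well. With an estimated correlation the list did not pass (adjusted p = 0.16). CCL2, a monocyte chemokine, had the largest fall of all genes named by size, from 186 ± 12.4 to 10.4 ± 1.02 FPKM (log2 fold change -4.04, limma adjusted p = 1.45e-08). CXCL8, a neutrophil chemokine, fell from 1639 ± 21.8 to 400.3 ± 7.17. NFKBIA, the inhibitor that NF-kB itself induces, fell from 35.2 ± 1.89 to 10.6 ± 0.551, and CSF2 from 27.8 ± 4.27 to 7.10 ± 0.913. The 3 members that rose were PTGS2, an inducible prostaglandin synthase, from 1.19 ± 0.110 to 13.3 ± 1.44, IRF1 from 51.0 to 162 and IER3 from 284 to 480 mean FPKM.

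The list of LUBAC and linear ubiquitin genes, which includes RNF31 itself, had 8 of 11 members lower and none higher (median log2 fold change -0.37, camera adjusted p = 0.017). The silenced RNF31 is among the 8, and the list was not tested without it. Adjusted over the list alone the count was also 8, and with an estimated correlation the adjusted p was 0.16. TNFAIP3, the deubiquitinase A20 and also an NF-kB target, fell from 24.6 ± 1.28 to 9.62 ± 0.633 FPKM. SPATA2, which links the deubiquitinase CYLD to LUBAC, fell by 0.60 on the log2 scale and TNIP1, also in the NF-kB list, by 0.58. Without the genes that carry any of 4 short sequences described with the largest falls, the list kept 7 members and did not pass (camera, adjusted p = 0.14). Their median log2 fold change was -0.25. The sequences were picked by their tie to lower values in these data and the list was smaller, so this does not test siRNA matches.

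Interferon-stimulated genes fell in the same cells, with 32 of 37 tested members lower and 2 higher (median log2 fold change -0.96, camera adjusted p = 3.52e-08). Adjusted over the list alone, 32 were lower and 3 higher, and the list also passed with an estimated correlation (adjusted p = 0.035). OAS1, an antiviral oligoadenylate synthetase, fell from 12.4 ± 1.39 to 0.92 ± 0.128 FPKM. IFITM1 fell from 48.6 ± 3.67 to 8.64 ± 1.61, and the antiviral GTPase MX1 from 10.6 ± 0.556 to 1.57 ± 0.208. MX2 fell by 2.04 on the log2 scale. IFITM1 has close paralogs that can share reads, and its value is uncertain for that reason. The transcription factor genes IRF7 and IRF9 did not follow the targets and rose, by log2 fold changes of 0.45 and 0.38.

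Antigen presentation genes were lower in 13 of 17 tested members and higher in 2 (median log2 fold change -0.59, camera adjusted p = 0.0039). Adjusted over the list alone the counts were 13 and 2, and with an estimated correlation the adjusted p was 0.27. TAPBP, the chaperone tapasin, fell from 89.9 ± 1.97 to 31.6 ± 1.19 FPKM, and the immunoproteasome subunit PSMB9 from 16.9 ± 0.221 to 7.19 ± 0.397. PSMB10 fell by 1.24 on the log2 scale and HLA-F by 1.19. The members that rose were TAP1 and HLA-E. Class I HLA genes are near-identical in sequence, so their values are uncertain.

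In the Hippo pathway, YAP1 rose from 23.6 ± 2.39 to 43.8 ± 4.35 FPKM (log2 fold change 0.86, limma adjusted p = 6.64e-05). Its paralog WWTR1, which encodes TAZ, measured 47.7 ± 5.08 and 40.2 ± 2.14, with a log2 fold change of -0.24 at an adjusted p of 0.035. That call was lost in most alternatives, among them those without siControl replicate 2 or 3 or siRNF31 replicate 2 or 3 (adjusted p from 0.079 to 0.12). Of 26 tested YAP and TAZ targets, 13 were higher and 8 lower, both over all genes and adjusted over the list alone (median log2 fold change 0.24, camera adjusted p = 0.017, and adjusted p = 0.16 with an estimated correlation). CCN2 rose from 331 ± 4.59 to 1281 ± 7.62 FPKM, CCN1 from 239 ± 11.7 to 742 ± 18.4, ANKRD1 from 14.9 ± 0.687 to 64.0 ± 0.764 and the endothelin gene EDN1 from 16.6 ± 1.12 to 79.3 ± 2.05. The member with the largest fall was NT5E, the ectonucleotidase CD73, from 126 to 42.1 mean FPKM. NT5E carries CTACACA and AAGTTTA, which are among the 4 short sequences described with the largest falls. In this target list 13 tested members carry any of the 4, and without them the median log2 fold change was 0.55. The 4 were picked by their tie to lower values in these data, so leaving out their carriers tends to raise a median. Of 21 Hippo pathway components, 9 were higher and 4 lower, also when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.12). Among them the kinase gene LATS2 rose by a log2 fold change of 0.85.

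**Figure D1:**
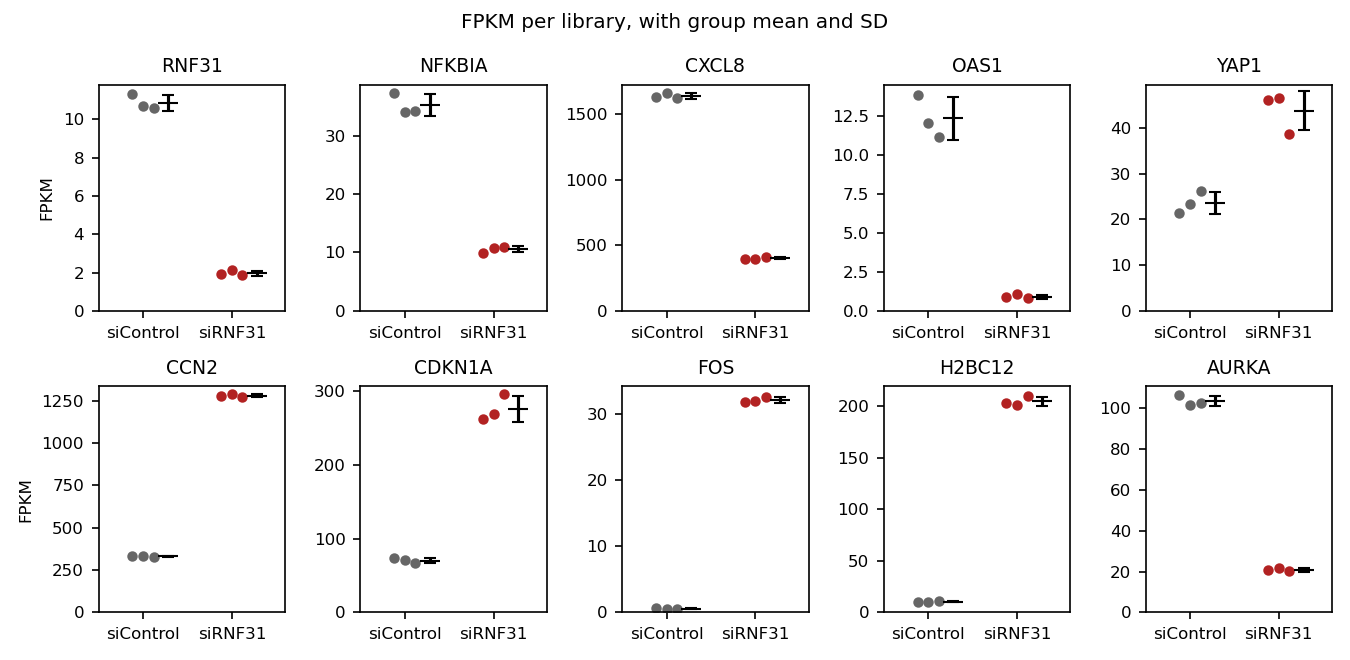
FPKM of 10 genes in each of the 3 siControl (grey) and 3 siRNF31 (red) libraries, on linear axes that start at 0, with the group mean and SD in black beside the points. RNF31, NFKBIA, CXCL8, OAS1 and AURKA lie lower and YAP1, CCN2, CDKN1A, FOS and H2BC12 higher in every siRNF31 library than in any siControl library.

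Immediate early genes, which encode transcription factors and phosphatases induced within minutes of a stimulus, rose as a list. Of 27 tested members 24 were higher and none lower, over all genes and adjusted over the list alone (median log2 fold change 1.16, camera adjusted p = 1.01e-12). With an estimated correlation the adjusted p was 0.073. EGR1 rose from 6.06 ± 0.386 to 197 ± 0.694 FPKM, FOS from 0.537 ± 0.064 to 32.2 ± 0.441, and FOSB from 0.53 ± 0.115 to 13.7 ± 0.533. ARC, a synaptic immediate early gene that stood outside the list, had the largest rise by the naming rule, from 4.52 ± 0.482 to 196 ± 16.5 FPKM (log2 fold change 5.16, limma adjusted p = 4.66e-09).

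Histone genes rose still further. Of 36 tested members of the histone list 31 were higher and none lower, over all genes and adjusted over the list alone (median log2 fold change 1.89, camera adjusted p = 1.43e-16). The list also passed with an estimated correlation (adjusted p = 0.016). H2BC4 rose from 0.79 ± 0.221 to 47.8 ± 2.07 FPKM and H2BC12 from 10.2 ± 0.471 to 205 ± 4.23. The FPKM summed over the list rose from 215 ± 14.1 to 1017 ± 41.3. The list was drawn up for replication-dependent histones, as a check on poly-A selection of the RNA. It also includes others, among them the linker variant H1-10, which is made outside S phase, and the testis gene H1-6. Histone copies are near-identical, and the split of reads between them is uncertain. H2AC19, for example, was listed at 0 in siControl and at 30.7 mean FPKM in siRNF31, while its copy H2AC18 went from 2.72 to 22.3 and did not pass. Other named genes with a large rise were MKNK2, a kinase of the translation factor eIF4E, from 6.59 ± 0.165 to 105 ± 5.20 FPKM, and TUFT1 from 1.36 ± 0.139 to 26.7 ± 0.576.

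ATF4 targets and amino acid response genes were higher in 22 of 24 tested members and lower in none, also when adjusted over the list alone (median log2 fold change 0.94, camera adjusted p = 1.48e-11, and adjusted p = 0.16 with an estimated correlation). ATF3, which also belongs to the immediate early list, rose from 6.21 ± 0.637 to 119 ± 0.799 FPKM. SESN2, a stress-induced inhibitor of mTORC1, rose from 6.61 ± 0.442 to 43.3 ± 1.65, the asparagine synthetase ASNS from 43.8 ± 1.74 to 214 ± 5.82, and DDIT3, the factor CHOP, from 16.8 ± 1.66 to 80.5 ± 6.29. ATF4 itself rose from 244 to 444 mean FPKM.

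ER chaperones and unfolded protein response genes passed as a list upward with smaller changes, 9 of 20 higher and 4 lower (median log2 fold change 0.15, camera adjusted p = 0.011). HERPUD1 rose from 37.2 ± 1.74 to 113 ± 0.937 FPKM, and HSPA5, the chaperone BiP, from 331 ± 5.60 to 656 ± 15.2. Of 29 hypoxia and glycolysis genes, 16 were higher and 2 lower (median 0.21, adjusted p = 0.011). The glycolytic genes that fell were ENO1, from 3038 ± 210 to 1298 ± 78.5 FPKM, and LDHA, from 1339 ± 58.5 to 1008 ± 33.7. For both lists the counts adjusted over the list alone were the same. With an estimated correlation the adjusted p was 0.16 for the ER list and 0.27 for the hypoxia list.

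Ribosomal protein genes shifted little. Of 77 tested, 13 were higher, 1 was lower and 63 did not pass, and adjusted over the list alone 2 were higher (median log2 fold change 0.10, camera adjusted p = 0.0073). With an estimated correlation the adjusted p was 0.83. The call was lost without siControl replicate 3 (adjusted p = 0.0995) or without siRNF31 replicate 3 (adjusted p = 0.12).

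Genes of the cell cycle went both ways. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 70.4 ± 3.57 to 276 ± 17.7 FPKM (log2 fold change 1.95, limma adjusted p = 1.49e-07). The ubiquitin ligase gene MDM2 rose by a log2 fold change of 0.36. Of 32 S phase genes 15 were higher and 9 lower, and 15 and 10 adjusted over the list alone (camera, adjusted p = 0.097). CCNE1, which encodes cyclin E1, rose from 6.97 ± 0.314 to 28.3 ± 1.16 FPKM, while the flap endonuclease FEN1 fell from 94.6 ± 4.52 to 57.0 ± 2.52. Of 32 genes of G2 and mitosis 4 were higher and 19 lower, also adjusted over the list alone (adjusted p = 0.10). The list passed with no filter on low values (adjusted p = 0.015) and with the GC and length trend removed (adjusted p = 0.038). The mitotic kinase AURKA fell from 104 ± 2.60 to 20.8 ± 0.804 FPKM and CCNA2 from 57.7 ± 1.53 to 31.9 ± 1.77.

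Matrix protease and integrin genes fell as a list, with 14 of 20 lower and 3 higher, also when adjusted over the list alone (median log2 fold change -0.60, camera adjusted p = 0.0073, and adjusted p = 0.16 with an estimated correlation). PLAU, the urokinase plasminogen activator, fell from 242 ± 6.76 to 48.7 ± 2.17 FPKM. The integrin subunits ITGA3 and ITGA5 fell from 90.9 ± 2.93 to 27.1 ± 0.988 and from 219 ± 9.0 to 83.1 ± 3.12. MMP3 rose from 9.59 to 20.4 mean FPKM. Genes of mesenchymal state did not pass as a list (8 higher and 15 lower of 28, 8 and 16 adjusted over the list alone, camera adjusted p = 0.30), but the hyaluronan receptor CD44 fell from 550.4 ± 17.3 to 247 ± 3.35 FPKM.

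**Figure D2:**
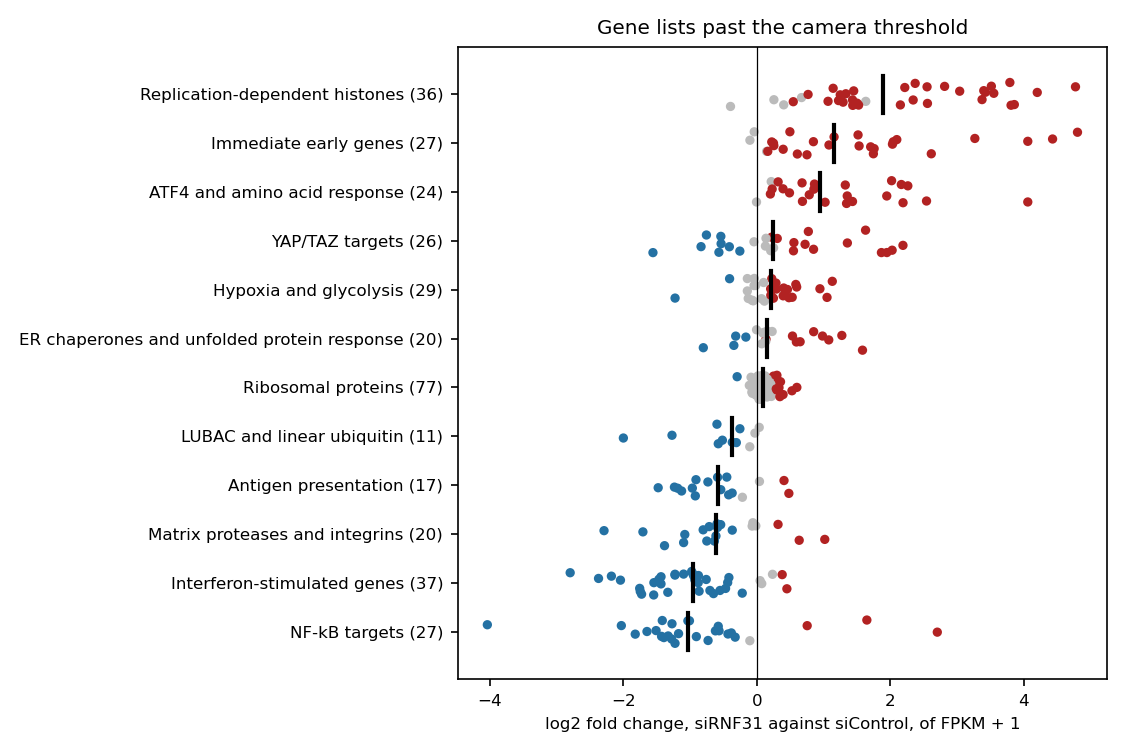
Log2 fold changes of FPKM + 1 for the tested members of the 12 gene lists that passed the camera test, with the number of tested members in brackets. Points are genes, red for higher, blue for lower and grey for not called, and black bars are list medians, which run from -1.03 for NF-kB targets to 1.89 for the histone list.

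The largest falls by the naming rule were, after CCL2, those of ACOT7, an acyl-CoA thioesterase, from 61.0 ± 5.62 to 7.33 ± 0.234 FPKM, OAS1, and CD81, a tetraspanin of the plasma membrane, from 188 ± 18.5 to 26.7 ± 2.92. YWHAZ, the 14-3-3 zeta protein, fell from 651 ± 18.3 to 131 ± 6.30. A 7-base sequence of the RNF31 mRNA, GCTACAC, also occurs in the annotated 3′ UTR of 4 of these 12 genes, namely ACOT7, CD81, YWHAZ and AURKA. The same sequence occurs in the 3′ UTR of ENO1. Over all genes with a searched 3′ UTR it was present in 17.7% of those lower by at least 2-fold and in 4.28% of the others. It was picked from a search of these same fold changes, so the 2 shares give no separate support. Another 3 sequences of the RNF31 mRNA, CTACACA, AAGTTTA and TGCTACA, were also tied to lower values after correction for 16189 sequences. So were CTACACT and ACTACAC, which do not lie in it, and 9 others were tied to higher values. CTACACT and ACTACAC share CTACAC with GCTACAC, and TGCTACA shares GCTACA with it, so they may not be signals apart from GCTACAC. GCTACAC and CTACACA overlap in the RNF31 mRNA, and the median log2 fold change was -0.06 both with and without AAGTTTA. Of the genes named by the rule here, TNFAIP3, OAS1, ACOT7, CD81 and YWHAZ, which fell, and YAP1 and ARC, which rose, carry TGCTACA. SPATA2, CCNA2, CD44, AURKA and YWHAZ, which fell, and LATS2, which rose, carry AAGTTTA. MDM2, which rose, and WWTR1, whose call was lost in most alternatives, carry both. CTACACA occurs in CD44, TNFRSF10B, ACOT7, AURKA and ENO1, which fell, and in PMAIP1, which rose. Without genes that carry any of the 4, 305 genes were higher and 291 lower by at least 2-fold among 7952 tested. Since the 4 were picked by their tie to lower values, these counts are no separate test. Among the most abundant genes, ACTB rose from 3426 ± 215 to 5960 ± 319 FPKM and TMSB4X, which carries AAGTTTA, fell from 1593 ± 155 to 817 ± 70.6.

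Other lists did not pass either. Among them were those of apoptosis, cholesterol synthesis, TGF-beta response, ribosome biogenesis, oxidative phosphorylation, NRF2 targets, the proteasome, autophagy and the markers of other cell types given next. Single members moved strongly. PMAIP1, the BH3-only protein NOXA, rose from 21.9 ± 1.05 to 125 ± 2.25 FPKM, while the death receptor gene TNFRSF10B fell from 62.6 ± 2.27 to 21.1 ± 0.142. HMOX1 rose from 61.5 ± 3.74 to 213 ± 13.7. Oxidative phosphorylation genes (2 higher and 11 lower of 30, and 1 and 11 adjusted over the list alone, camera adjusted p = 0.14) passed without siControl replicate 3 (adjusted p = 0.035) or siRNF31 replicate 3 (adjusted p = 0.044), and also with no filter, under 2 of the scalings and with the GC and length trend removed (adjusted p from 0.028 to 0.040).

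Markers of other cell types were measured alongside. Of 9 tested fibroblast and endothelial markers, 1 was higher and 7 lower, also adjusted over the list alone (median log2 fold change -0.29, camera adjusted p = 0.12). Several were abundant in all libraries. COL1A1 averaged 1049.9 FPKM in siControl and 668 in siRNF31, COL3A1 rose from 204 ± 10.6 to 328 ± 12.4, and PDGFRB fell from 23.4 ± 0.594 to 9.14 ± 0.178. Endothelial VWF and CDH5 stayed below 1 FPKM, and PECAM1 fell from 1.49 to 0.573 mean FPKM. Of 5 tested epithelial genes 2 were higher and 1 lower (adjusted p = 0.59). The keratin gene KRT18 fell from 166.9 to 90.6 mean FPKM, KRT7 rose from 3.61 to 6.16, KRT8 averaged 10.2 in both groups, and KRT19, EPCAM and CDH1 were below 1 FPKM. Of 5 tested luminal breast markers 1 was higher and 2 lower (adjusted p = 0.90). The leukocyte list had 4 tested members, too few for the test. Of these LCP1 rose from 0.517 to 1.94 and CORO1A from 1.92 to 3.53 mean FPKM, and CD14 fell from 1.24 to 0.523. CD68 averaged 39.9 FPKM in siControl and 35.4 in siRNF31 and did not pass. PTPRC, which encodes CD45, averaged 0.287 and 0.377 FPKM. No mitochondrially encoded transcript was among the genes listed.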

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

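The scalings to a common sum and by quantiles, the removal of the GC and length trend, the fit without both libraries that stood apart and the fit without genes carrying the short 3′ UTR sequences were chosen after seeing the data. The alternatives written for read counts were not run because the files hold FPKM. The counts of higher, lower and 2-fold changed genes stayed within 1.5 times the main value under all alternatives except 1. Without genes that carry any of the 4 sequences of the RNF31 mRNA, 291 genes were lower by at least 2-fold, among the fewer genes tested. These sequences had been picked by their tie to lower values. Median of ratios scaling gave 3592 higher and 3558 lower genes, 457 and 406 of them by at least 2-fold, and quantile normalization 3529 and 3740, with 439 and 437 by at least 2-fold. Leaving out 1 library at a time gave 2607 to 3018 higher and 3603 to 4127 lower genes, and 392 to 410 and 484 to 501 by at least 2-fold. The RNF31 log2 fold change ran from -2.04 to -1.97 without 1 library, and was -2.41 with a pseudocount of 0.1. Without both libraries that stood apart, 3401 genes were higher and 4513 lower, 404 and 491 of them by at least 2-fold. Of 29 lists, 12 passed in the main test and 12 without any 1 library, 2 with an estimated correlation, and 22 with fry, which does not set a list against other genes. The list of ribosomal proteins was lost under quantile normalization (adjusted p = 0.39). Lists that passed only under alternatives, besides those under fry alone, were G2 and mitosis, oxidative phosphorylation, the proteasome (adjusted p = 0.030 with no filter and 0.029 with quantiles) and the fibroblast and endothelial markers (adjusted p = 0.045 with quantiles). Of 139 named genes other than RNF31, 129 kept direction and side of the threshold under every alternative that tested them, and those with any of the 4 sequences were not tested in the fit that left such genes out. SHARPIN, never called, changed sign, with log2 fold changes of 0.044 under median of ratios scaling, 0.039 under quantile normalization, 0.060 with the trend removed and -0.073 to 0.017 without 1 library, and the cause was not tested.

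With the replicate number as a block, 2480 genes were higher and 3497 lower, 402 and 489 of them by at least 2-fold, RNF31 kept its log2 fold change of -2.0, and 12 lists passed. The numbers did not pair the libraries. Deviations from the group means correlated at -0.568, 0.124 and -0.629 across genes for the libraries with numbers 1, 2 and 3, and siControl replicate 1 correlated best with siRNF31 replicate 3 (0.675). The depth is unknown, so whether low genes were missed for lack of reads cannot be judged.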

Other observations

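The gene lists in the next paragraphs and the tests of histone copies, S phase, scaling, stromal markers, the cell line and the siControl sites were chosen only after the results were seen. Genes of the actin cytoskeleton and targets of the serum response factor SRF were mostly higher, 19 of 24 higher and 1 lower (median log2 fold change 0.52, adjusted p = 0.11 with an estimated correlation). ACTA2 rose from 39.4 to 94.9 mean FPKM, TPM4 from 200.4 to 993 and SRF itself from 21.7 to 43.5. All 5 tested metallothioneins, small proteins that bind zinc and copper, were higher (adjusted p = 0.28 with an estimated correlation), with MT2A going from 1124 to 2847 mean FPKM and MT1X from 96.3 to 478. Metallothionein copies are near-identical and can share reads. Of 346 tested zinc finger genes whose symbols start with ZNF, 183 were higher and 38 lower (median log2 fold change 0.25, adjusted p = 0.11 with an estimated correlation).

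Cytokine receptor genes went the opposite way, with 17 of 20 lower and 1 higher (median log2 fold change -0.71, adjusted p = 0.064 with an estimated correlation). IFNGR2, a chain of the interferon gamma receptor, fell from 62.7 to 16.8 mean FPKM, OSMR from 63.7 to 17.0 and IL27RA from 6.55 to 0.873. Of 16 tested tetraspanins 12 were lower and 3 higher (median log2 fold change -0.48, adjusted p = 0.28 with an estimated correlation). CD82 fell from 81.6 ± 4.89 to 15.1 ± 1.21 FPKM (SD, n = 3). Cytosolic heat shock genes did not move together, with 5 higher and 6 lower of 15.

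The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the 1 with most genes: 3022 higher, 4141 lower, and 401 and 489 by at least 2-fold, against 0 in every other split by limma in each of these counts. Every other split mixes libraries of both groups, so the group difference enters the spread within its sides and hides changes. These gene counts therefore cannot test chance. For the gene lists the real split gave 12, and 2 of the 10 splits, the real one included, gave as many. The highest other split gave 13, in which libraries of both groups stand on each side. Mixed splits keep a part of the group difference, so they do not show how many lists chance alone would give.

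Many genes fell by at least 2-fold, and a short sequence of the silencing RNA is a candidate explanation for part of them, since an siRNA can repress mRNAs whose 3′ UTR matches bases 2 to 8 of its guide strand. Across 11173 genes, the 7-base sequence most strongly tied to lower values was GCTACAC (t = -12.62, rank 1 of 16189). It lies in the RNF31 mRNA, but so does GGAGAAA, the sequence most strongly tied to higher values (t = 6.81). Of the 9 sequences tied to higher values, all but CGCCGCC contain GGAGA, as does the site TCGGAGAA below. GGAGAAA lies in 2611 genes and TCGGAGAA in 72, and whether GGAGAAA is a signal apart from that site was not tested. The median log2 fold change graded from -0.23 with the 8-base GCTACACA over -0.21, -0.12 and -0.07 with the shorter sites to -0.05 with none. GCTACAC was picked by its tie to these same fold changes, so lower medians of its carriers give no separate support. At least 406 genes were lower by at least 2-fold under each of 3 other scalings, so the choice among these does not account for the falls. They moved the median log2 fold change of all genes little, from -0.06 to between -0.079 and 0.006. FPKM is relative, so none of them can show a change in the total RNA of the cells. Since 59.2% of the 2-fold lower genes carry none of the 4 sequences against 70.1% of the others, direct matches may account for only a part. An effect of losing RNF31 stays open for the rest and was not tested apart. TCGGAGAA could be a site of the siControl. Of the 72 genes with it, 12.5% were higher by at least 2-fold, against 3.0% of genes with no such site. It was picked from the same scan, so these shares give no separate support. Whether it is a siControl site stays open because the siControl sequence was not used here.

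The rise of immediate early and histone genes could be technical or biological. GC content and transcript length argue little, since with their trend removed the lower of the 2 list medians was 1.22 against 1.16 before. That is the immediate early median, and the histone median went from 1.89 to 1.78. Reads that merely moved between histone copies would leave the sum unchanged, and the sum rose 4.73-fold. A larger share of cells in S phase would raise S phase genes with the histones. The upper quartile of the S phase list was 0.405 against a histone median of 1.89. How far S phase genes would rise beside histones was not known, and 15 of 32 were higher and 9 lower. A larger S phase share therefore cannot be excluded. An effect of RNF31 loss, of either siRNA or of handling at harvest stays open, because each goes with the groups. For the histones, whose list was fixed as a check on poly-A selection, a difference in that selection between groups was not tested and stays open too.

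The cells expressed stromal genes at levels that invite a second look at the line. The lowest COL1A1 value in any library was 651.85 FPKM, POSTN averaged 239 in siControl, KRT19 and ARHGDIB averaged 0.013 and 0.347 there, but the epithelial keratin gene KRT18 averaged 166.9. A difference in the share of stromal cells alone would move the markers alike, and the log2 fold changes of 8 markers spread over 1.94, from PDGFRB down to COL3A1 up. With 63.1% of tested genes called, the markers may also change within cells. The spread therefore cannot exclude a difference in share beside such changes. Another line than the labelled one, or a mesenchymal state of this stock, may underlie the levels, and this stays open because no reference profile of the line was used here.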
